A study of Mus musculus with 6 samples.

How the data were processed

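Expression was measured on Illumina mouse BeadChips in 6 samples, 2 each of mESCs, cytokine-induced PGCLCs and Nanog-induced PGCLCs, and samples were grouped by their labels. Per the labels' protocols, total RNA was purified on columns, amplified and labelled with biotin. The deposited intensity values are scanner summaries per probe that, from the values, were neither background corrected nor normalized between arrays. The deposited detection p-values rank each probe among the negative control beads of its array, per the file headers and the values. The authors' value table holds log2 values that, from the values, were quantile normalized, since its 6 columns hold the same values within 0.001 (median 8.982). It lists exactly the 11542 probes with a detection p below 0.01 on at least 1 array, and limma is named in the submitters' processing notes without a version. Its background treatment is not given in the sources used here. Its columns correlated at 0.985 to 0.990 with the values normalized here and at 0.9994 to 0.9999 with the log2 raw intensities. The authors' values thus lie close to ones without background correction, which argues against a correction like the one used here.

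Background was corrected here from the 45281 raw intensities per array with the normexp model of limma 3.58.1 in R 4.3.3, with the negative control level inferred from the detection p-values (936 controls implied) and an offset of 16. Quantile normalization and log2 transformation followed. Probes with a detection p below 0.01 on at least 2 of the 6 arrays were kept (10673). Gene names came from the platform annotation of the probes in the authors' table, of which 10057 had 1 symbol, 4 several and 1481 none. Of these probes, 10050 matched a RefSeq gene by Entrez identifier and 0 symbols changed. Each gene was read by its named probe with the highest mean, which gave 6823 genes, and 1359 kept probes without a name were tested apart. Of 1905 genes with several probes, 45, 44 and 3 called genes had another probe called in the opposite direction in the comparisons of Nanog PGCLCs with mESCs, cytokine PGCLCs with mESCs, and Nanog with cytokine PGCLCs. The panel genes Prdm1 and T had no named probe among those tested. No genome was used here, so no coordinates are given.

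The 3 comparisons were fitted with limma (lmFit and eBayes) in 1 model of 3 groups, with 3 residual and 5.16 prior degrees of freedom. Tests were two-sided with Benjamini-Hochberg adjustment over all genes, and a gene was called at an adjusted p below 0.05. A gene whose probes all had a detection p of at least 0.01 on both arrays of a group was taken as not detected there. Its difference from a brighter group is given as "at least N-fold", with the adjusted p of the fit. That bound sets the bright group's mean against, per array, the higher of the lowest normalized signal among detected probes and the dim probe's own signal. No fold is given where the bound is under 1 or neither group detected the gene, although such a gene can still be called. Named genes were, per comparison, the 12 largest increases and 12 largest decreases among called genes with a symbol, a change of at least 2-fold, separated arrays and detection on both arrays of the higher group. Added were up to 4 members with the smallest adjusted p of each list described and a panel of 14 genes, and any other gene is said to be chosen after its values were seen.

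The 27 gene lists covered early and late germ cell genes, core and naive pluripotency, primed epiblast, primitive streak, endoderm, neural and surface ectoderm, trophoblast, fibroblast and matrix, endothelial and blood, Hox, cleavage stage and imprinted genes, DNA and histone methylation, targets of BMP, WNT, FGF and LIF signalling, stress, p53, cell cycle, glycolysis, oxidative phosphorylation, cholesterol synthesis and cell adhesion. Lists with at least 5 tested members (22) were tested with camera at a preset correlation of 0.01, adjusted over lists within a comparison, and again with an estimated correlation. With the preset value 6, 3 and 8 lists were called, and with the estimated correlation 0, 0 and 0, and with the latter 4, 3 and 5 lists had an unadjusted p below 0.05. Some genes belong to several lists, such as Dnmt3b, Gata2 and Klf4. The groups, comparisons, lists, naming rule and most alternatives were fixed before the data were examined. Lists of red cell, oxidative stress and actin genes were added later, prompted by genes seen among the largest changes, and left out those already seen.

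The workflow was tested on simulated data for the 6823 genes, with 200 genes changed. In the comparison of Nanog PGCLCs with mESCs, 98.5% of 2-fold changes, 71.6% of 1.41-fold changes and 3.0% of 1.19-fold changes were recovered, and 3.3% of calls were false. For cytokine PGCLCs against mESCs the shares were 100%, 71.6% and 1.5%, with 7.9% false calls, and for Nanog against cytokine PGCLCs 100%, 71.6% and 4.5%, with 6.3% false calls. In the data, 54.1%, 54.7% and 22.6% of genes were called in these comparisons, many more than were changed in the simulation. The adjusted threshold is then less strict, so the shares recovered need not hold for the data. In a simulated comparison of Nanog PGCLCs with mESCs, the shifted list was called, and so was 1 of 21 unshifted lists. Alternatives were no background correction, an offset of 50, median scaling, cyclic loess, the authors' table, other filters on dim probes, every probe by itself, a variance trend, a stricter threshold, the replicate number as a block, each array left out, and only the groups compared. The other filters could add only named probes, all detected on at least 1 array. They thus test the filter only in part, since probes detected on no array could not enter. Groups of 2 arrays are too small for a test of other splits of the samples or of stray arrays.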

Results

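Gene expression was measured on Illumina mouse BeadChip arrays in 3 groups of male mouse cells, all carrying a Nanog transgene, with 2 arrays per group. The first group was mouse embryonic stem cells (mESCs) kept in N2B27 medium with the cytokine LIF at 1000 U/ml, the GSK3 inhibitor CHIR99021 at 3 µM and the MEK inhibitor PD0325901 at 1 µM. The other groups were primordial germ cell-like cells (PGCLCs), a culture model of the founder cells of sperm and eggs, collected on day 4 of induction from epiblast-like cells. Cytokine PGCLCs were induced with BMP4 and BMP8A at 500 ng/ml each, SCF at 100 ng/ml, EGF at 50 ng/ml and LIF at 1000 U/ml. Nanog PGCLCs were induced by switching on Nanog, a pluripotency transcription factor, with doxycycline at 0.7 µg/ml in the same base medium. Whether the PGCLCs were sorted is not given in the sources used here. The labels do not say that the replicates came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

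Median raw intensity was 233.5 and 280.6 on the mESC arrays, 239.5 and 230.7 on the cytokine PGCLC arrays, and 226.2 and 294.3 on the Nanog PGCLC arrays. Of 45281 probes, 9220 and 8788 were detected in mESCs, 9871 and 10028 in cytokine PGCLCs, and 9896 and 10021 in Nanog PGCLCs. Across genes, normalized log2 intensities correlated at r = 0.991 to 0.994 between replicates and at 0.969 to 0.970 between cytokine and Nanog PGCLCs. The correlation was 0.923 to 0.924 between mESCs and cytokine PGCLCs and 0.920 to 0.923 between mESCs and Nanog PGCLCs (genes are not independent replicates). The first principal component held 70.9% of the variance and the second 20.8%. After filtering, 6823 genes were tested in each comparison, and the number of arrays limits the precision of every value.

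Nanog, the induced gene, was read by 2 probes that moved in different directions. On the probe used for the gene, normalized log2 intensity was 12.33 and 12.47 in mESCs, 12.52 and 12.52 in cytokine PGCLCs, and 12.04 and 12.24 in Nanog PGCLCs. On the second probe it was 11.48 and 11.55 in mESCs, 10.93 and 10.79 in cytokine PGCLCs, and 12.72 and 12.59 in Nanog PGCLCs. The second probe was higher in Nanog PGCLCs by 1.14 ± 0.10 log2 units against mESCs (adjusted p over probes = 6.41e-05, limma) and by 1.80 ± 0.10 against cytokine PGCLCs (adjusted p = 3.17e-05). Where each probe lies relative to the transgene is not known here, so this checks the group labels only with that limit.

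**Figure D1:**
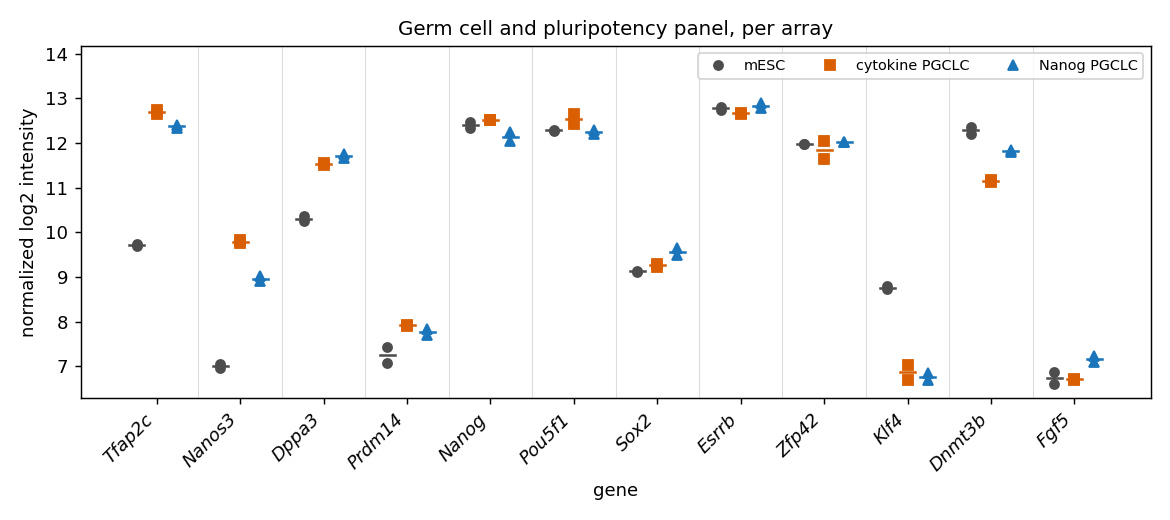
Normalized log2 intensity (y axis) of the 12 measured panel genes (x axis) on each array of mESCs (circles), cytokine PGCLCs (squares) and Nanog PGCLCs (triangles), with a short line at each group mean. Mean Tfap2c lay at 9.72 in mESCs, 12.69 in cytokine PGCLCs and 12.37 in Nanog PGCLCs, and levels of different genes are not comparable because each has its own probe.

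The first comparison asked how Nanog-induced PGCLCs differ from the mESCs, and most early germ cell genes were higher in the PGCLCs. Tfap2c, a transcription factor required for germ cell formation, was higher 6.27-fold (log2 fold change 2.65 ± 0.09), and Nanos3, an RNA-binding protein that protects early germ cells, was higher 3.87-fold (log2 fold change 1.95 ± 0.10) (± SE, n = 2 arrays per group, limma adjusted p = 8.47e-07 and 2.66e-06). The size of the Tfap2c change depended on the probe, since its other probes gave 1.06 and 2.80 log2 units. Dppa3, a maternal factor expressed in germ cells, was higher 2.64-fold (SE 0.09 log2 units), and the X-linked homeobox genes Rhox9 and Rhox6 were higher 9.59-fold and 3.56-fold. Of the 15 tested early germ cell genes, 11 were higher, 0 were lower and 4 were not called, with 11 higher and 0 lower when adjusted over the list alone. The list of early germ cell genes had a camera adjusted p = 0.000382, and adjusted p = 0.243 with an estimated correlation. The germ cell regulator Prdm14 was higher by 0.51 ± 0.13 log2 units, a call lost when mESC replicate 2 (0.33) or Nanog PGCLC replicate 1 (0.44) was left out. For pluripotency regulators the log2 fold changes were -0.03 ± 0.10 for Pou5f1, 0.06 ± 0.09 for Esrrb and 0.05 ± 0.13 for Zfp42, none of them called. The used Nanog probe was at -0.26 ± 0.10 (adjusted p = 0.0643), which was called without Nanog PGCLC replicate 2 (-0.36), without background correction, with an offset of 50, with cyclic loess, with the authors' value table, with a variance trend and with the brighter arrays as a block (-0.33 to -0.25). Sox2 was higher by 0.44 ± 0.10, while Klf4, a naive pluripotency factor, was at least 3.65-fold lower (adjusted p = 8.01e-06). The core pluripotency list had 4 higher, 2 lower and 7 not called (4 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.617), with Dppa4 higher by 0.93 ± 0.09 and the RNA-binding protein Lin28a lower at -0.99 ± 0.10. The naive pluripotency list had 4 higher, 8 lower and 3 not called (4 higher and 8 lower adjusted over the list alone, camera adjusted p = 0.225), with Tbx3 lower at -1.45 ± 0.11 and Tfcp2l1 at -0.98 ± 0.09.

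Most genes of the primed epiblast list were also higher. Lefty1, a secreted inhibitor of Nodal, was higher 4.68-fold (log2 fold change 2.23 ± 0.09), its relative Lefty2 2.22-fold, and the tight junction gene Cldn6 at least 4.67-fold. The de novo DNA methyltransferase gene Dnmt3b moved the other way, at -0.47 ± 0.10. Of the 9 tested primed epiblast genes, 7 were higher, 1 was lower and 1 was not called, with 7 higher and 1 lower when adjusted over the list alone. The list of primed epiblast genes had a camera adjusted p = 0.0113, and adjusted p = 0.243 with an estimated correlation. Fgf5, an epiblast marker, was among the members called higher, at least 1.04-fold, but its call was lost with the authors' value table (log2 fold change 0.15), without mESC replicate 1 (0.30) and without Nanog PGCLC replicate 2 (0.37). In the glycolysis and hypoxia list, Pdk1, a kinase that holds back pyruvate oxidation, was higher 3.63-fold (log2 fold change 1.86 ± 0.10), the phosphofructokinase gene Pfkl 2.23-fold and the hypoxia-induced Ankrd37 at least 1.59-fold. Of the 15 tested glycolysis and hypoxia genes, 9 were higher, 1 was lower and 5 were not called, with 9 higher and 2 lower when adjusted over the list alone. The list of glycolysis and hypoxia genes had a camera adjusted p = 0.0161, and adjusted p = 0.243 with an estimated correlation. With arrays scaled to the same median in place of quantile normalization, that list was not called (adjusted p = 0.0818, the highest of a range from 0.00748 over its 15 alternatives with the preset correlation).

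Most targets of WNT and of LIF and STAT3 signalling and most genes of cholesterol synthesis were lower in Nanog PGCLCs. In this comparison LIF, the GSK3 inhibitor CHIR99021 and the MEK inhibitor PD0325901 are listed for the mESCs only. Differences in WNT, LIF and ERK targets, and in every other list against mESCs, therefore cannot be told apart from the change of medium. The WNT-induced transcription factor gene Sp5 was at least 3.72-fold lower, the cyclin gene Ccnd1 changed by -2.24 ± 0.10 log2 units, and Notum, a secreted WNT inhibitor, by -1.46 ± 0.09. Of the 6 tested WNT target genes, 0 were higher, 5 were lower and 1 was not called, with 0 higher and 6 lower when adjusted over the list alone. The list of WNT target genes had a camera adjusted p = 0.000382, and adjusted p = 0.243 with an estimated correlation. Among LIF and STAT3 targets, the adhesion receptor gene Icam1 was at least 3.47-fold lower and Socs3, a feedback inhibitor of STAT3 signalling, changed by -0.97 ± 0.09. Of the 11 tested LIF and STAT3 target genes, 0 were higher, 8 were lower and 3 were not called, with 0 higher and 8 lower when adjusted over the list alone. The list of LIF and STAT3 target genes had a camera adjusted p = 0.000419, and adjusted p = 0.243 with an estimated correlation. In cholesterol synthesis, the sterol sensor Insig1 changed by -1.26 ± 0.09, farnesyl diphosphate synthase (Fdps) by -1.22 ± 0.09 and the demethylase Cyp51 by -1.05 ± 0.11. Of the 12 tested cholesterol synthesis genes, 0 were higher, 9 were lower and 3 were not called, with 0 higher and 9 lower when adjusted over the list alone. The list of cholesterol synthesis genes had a camera adjusted p = 0.000382, and adjusted p = 0.243 with an estimated correlation. The BMP and SMAD, imprinted, DNA methylation, primitive streak, trophoblast and blood lists were not called (camera adjusted p = 0.682, 0.921, 0.406, 0.225, 0.365 and 0.504), and the imprinted genes had a median of -0.09 but a mean of 0.13. The FGF and ERK target list had 5 higher, 1 lower and 2 not called and was not called (5 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.0997), although its member Dusp4, a phosphatase that acts on MAP kinases, was higher at least 7.93-fold.

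Among the other genes with the largest increases, Kndc1 was higher at least 8.88-fold, the nucleosome-binding protein gene Hmgn5 12.8-fold (log2 fold change 3.68 ± 0.09) and the WNT receptor gene Fzd7 at least 4.29-fold. Among the largest decreases, the homeobox gene Crxos was at least 5.57-fold lower, the fatty acid desaturase gene Scd1 at least 6.51-fold lower and vimentin (Vim) at least 4.29-fold lower. Ddah1, which breaks down dimethylarginine, changed by -3.40 ± 0.09 log2 units and the matrix glycoprotein gene Sparc by -2.67 ± 0.09. In all, 1925 genes were higher and 1769 lower (54.1% of those tested), and 465 and 243 of them differed at least 2-fold by the fitted values. Of these, 308 were not detected on either array of the lower group, so their fitted folds are no bounds. With median scaling the counts were 2779 higher and 854 lower (76.5% higher, against 52.1%), and without background correction 101 and 55 genes differed at least 2-fold.

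The second comparison set cytokine-induced PGCLCs against the same mESCs, and most early germ cell genes were again higher. Tfap2c was higher 7.82-fold (log2 fold change 2.97 ± 0.09), Nanos3 6.88-fold (log2 fold change 2.78 ± 0.10), Rhox9 8.98-fold (log2 fold change 3.17 ± 0.14) and Dnd1, an RNA-binding protein that germ cells need to survive, 3.79-fold (log2 fold change 1.92 ± 0.09) (± SE, n = 2 arrays per group, limma adjusted p from 6.53e-07 to 2.41e-06). On the other Tfap2c probes the change was 0.99 and 3.19 log2 units. Of the 15 tested early germ cell genes, 13 were higher, 1 was lower and 1 was not called, with 13 higher and 1 lower when adjusted over the list alone. The list of early germ cell genes had a camera adjusted p = 2.41e-05, and adjusted p = 0.194 with an estimated correlation. Prdm14 was higher by 0.67 ± 0.13. Rhox5, named after its values were seen, was the member called lower, at -1.18 ± 0.11. Klf4 changed by -1.90 ± 0.12 and Dnmt3b by -1.13 ± 0.10 (adjusted p = 1.06e-05 and 3.74e-05). The size of the Klf4 change is uncertain, since its mean of 6.86 in cytokine PGCLCs lay under the lowest signal of detected probes there (6.9 and 6.87). The log2 fold changes were 0.12 ± 0.10 for the used Nanog probe, 0.25 ± 0.10 for Pou5f1, 0.14 ± 0.10 for Sox2, -0.11 ± 0.09 for Esrrb and -0.13 ± 0.13 for Zfp42, none of them called. The second Nanog probe was called lower in cytokine PGCLCs, at -0.657 (limma adjusted p over probes = 0.00102). Whether Nanog changed there thus depends on the probe. Pou5f1 was called without cytokine PGCLC replicate 2 (0.36), without background correction (0.24), with an offset of 50 (0.25), with the authors' value table (0.24) and with a variance trend (0.25). Fgf5 was not detected on either array of mESCs or of cytokine PGCLCs. The core pluripotency list had 1 higher, 1 lower and 11 not called (1 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.465) and the naive list 2 higher, 8 lower and 5 not called (2 higher and 8 lower adjusted over the list alone, camera adjusted p = 0.0757).

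Most LIF and STAT3 targets were lower in cytokine PGCLCs than in mESCs, and LIF was in both media. CHIR99021 and PD0325901 are listed for the mESCs only, so the media differed in these too. BMP4, BMP8A, SCF and EGF are listed for the cytokine PGCLCs and not for the mESCs. Here too, no list difference from mESCs can be told apart from the change of medium. The transcription factor gene Stat3 was at least 4.03-fold lower, Icam1 at least 3.46-fold lower, and Socs3 changed by -1.57 ± 0.09 log2 units. Of the 11 tested LIF and STAT3 target genes, 0 were higher, 9 were lower and 2 were not called, with 0 higher and 9 lower when adjusted over the list alone. The list of LIF and STAT3 target genes had a camera adjusted p = 2.41e-05, and adjusted p = 0.194 with an estimated correlation. Insig1 changed by -1.36 ± 0.09, Fdps by -1.18 ± 0.09 and Cyp51 by -1.18 ± 0.11 in the cholesterol synthesis list. Of the 12 tested cholesterol synthesis genes, 0 were higher, 9 were lower and 3 were not called, with 0 higher and 9 lower when adjusted over the list alone. The list of cholesterol synthesis genes had a camera adjusted p = 0.000211, and adjusted p = 0.194 with an estimated correlation. Several BMP and SMAD targets were higher, with Id1, a helix-loop-helix inhibitor induced by BMP, at least 8.60-fold, Msx1 at least 2.31-fold, Id3 at least 1.93-fold and Gata2 5.59-fold (log2 fold change 2.48 ± 0.17). This list had 5 higher, 2 lower and 2 not called, and 5 higher and 2 lower adjusted over the list alone, and was not called. The list of BMP and SMAD target genes had a camera adjusted p = 0.0537, and adjusted p = 0.439 with an estimated correlation. The embryonic globin genes Hba-x and Hbb-bh1 were higher at least 3.38-fold and at least 4.94-fold (adjusted p = 4.09e-07 and 3.54e-06), and their list, endothelial and blood genes, had 2 higher, 1 lower and 2 not called (2 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.397). Of the imprinted genes, Peg3 was higher 6.02-fold (log2 fold change 2.59 ± 0.09) and Phlda2, which restrains placental growth, 4.25-fold (log2 fold change 2.09 ± 0.10), and the list had 6 higher, 2 lower and 2 not called (6 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.226). The DNA methylation and oxidation list had 1 higher, 5 lower and 1 not called (2 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.0885), with Dnmt3l, a cofactor of the de novo methyltransferases, at -1.33 ± 0.09. The WNT, primed epiblast, glycolysis, primitive streak, trophoblast and FGF lists were not called (camera adjusted p = 0.346, 0.273, 0.226, 0.938, 0.465 and 0.0757). The streak genes had a median of -0.20 but a mean of 0.18, and the trophoblast genes a median of -0.04 but a mean of 0.66.

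The largest increases also included the adaptor subunit gene Ap3b2, at least 6.50-fold, the chemokine gene Cxcl12, at least 3.50-fold, and the Notch target Hey1, at least 4.36-fold. Among the largest decreases, Mras was at least 6.08-fold lower, the transglutaminase gene Tgm1 at least 4.76-fold lower and the antioxidant enzyme gene Gpx2 at least 4.48-fold lower, while Khdc3, a maternal-effect gene, changed by -3.20 ± 0.14 log2 units. In all, 2040 genes were higher and 1694 lower (54.7%), and 476 and 249 of them differed at least 2-fold by the fitted values, 329 of which were not detected on either array of the lower group. With median scaling the counts were 2611 higher and 973 lower (72.9% higher, against 54.6%), and without background correction 82 and 68 genes differed at least 2-fold. With the preset correlation 3 lists were called, which became 7 with median scaling, without background correction, with the authors' value table and with a variance trend, 5 with cyclic loess, and 5 without mESC replicate 1 or cytokine PGCLC replicate 2.

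The third comparison set the PGCLC groups against each other, and most BMP and SMAD targets were lower in Nanog PGCLCs than in cytokine PGCLCs. Id1 was at least 9.995-fold lower, Msx1 at least 2.69-fold lower, Id3 at least 2.24-fold lower and Id2 at least 1.62-fold lower (n = 2 arrays per group, limma adjusted p from 4.66e-07 to 4.27e-05). The transcription factor gene Gata2 changed by -2.35 ± 0.17 log2 units and Tbx3 by -0.997 ± 0.11, and the ligand gene Bmp4, named after its values were seen, was the member called higher, by 0.75 ± 0.09. Of the 9 tested BMP and SMAD target genes, 1 was higher, 7 were lower and 1 was not called, with 1 higher and 7 lower when adjusted over the list alone. The list of BMP and SMAD target genes had a camera adjusted p = 7.67e-05, and adjusted p = 0.193 with an estimated correlation. Of the PGCLC groups, BMP4 and BMP8A were given only to the cytokine PGCLCs, as were SCF, EGF and LIF. Doxycycline is listed for the Nanog PGCLCs only. Differences between these groups cannot be assigned to any of these alone. Embryonic globin genes differed in the same direction, Hba-x being at least 3.93-fold lower and Hbb-bh1 at least 5.74-fold lower in Nanog PGCLCs, and Hbb-y, found by the rule of largest changes, at least 4.07-fold lower. The endothelial and blood list had 0 higher, 2 lower and 3 not called, and 0 higher and 2 lower adjusted over the list alone. The list of endothelial and blood genes had a camera adjusted p = 0.0125, and adjusted p = 0.193 with an estimated correlation, and both of its called members were globins. Its member Hba-a1 had normalized log2 intensities of 8.81 and 8.95 in cytokine PGCLCs and 6.39 and 6.69 in Nanog PGCLCs, where it was not detected. It was not called (adjusted p = 0.221), with 11.41 on mESC replicate 1 and 6.35 on mESC replicate 2 widening the pooled spread, and was called, at the same fitted -2.34, without mESC replicate 1, without mESC replicate 2 and with the PGCLC groups fitted alone.

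**Figure D2:**
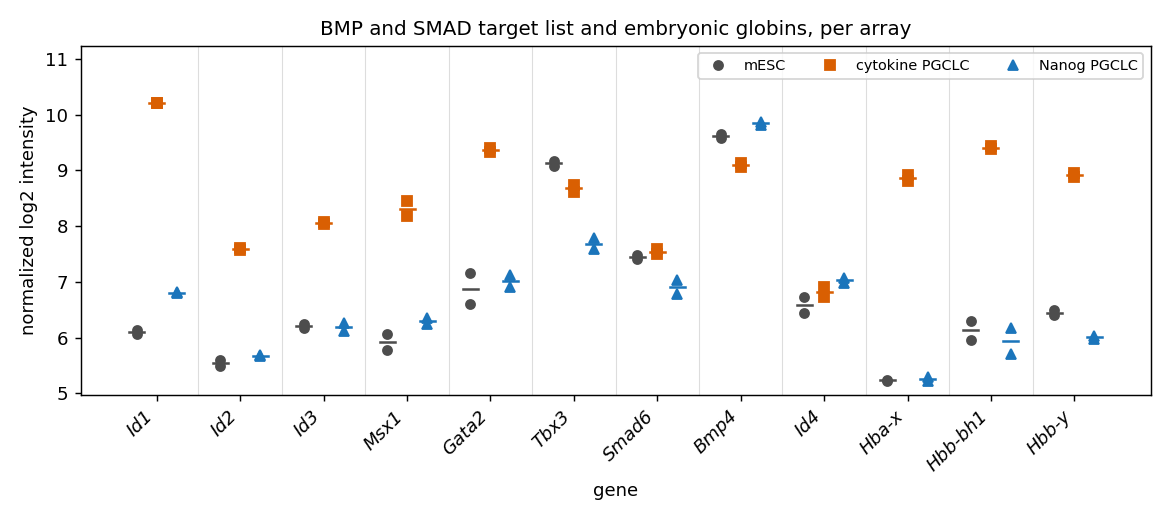
Normalized log2 intensity (y axis) of the 9 tested BMP and SMAD targets and 3 embryonic globin genes (x axis) on each array of mESCs (circles), cytokine PGCLCs (squares) and Nanog PGCLCs (triangles), with a short line at each group mean. Hba-x lay at 8.81 and 8.92 in cytokine PGCLCs and at 5.28 and 5.23 in Nanog PGCLCs, where it was not detected, so the lower points of such genes mark no measured level.

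Most targets of WNT signalling, trophoblast and keratin genes and imprinted genes were also lower in Nanog PGCLCs than in cytokine PGCLCs. Axin2, a feedback inhibitor of WNT signalling, was at least 3.29-fold lower, and Tnfrsf19 changed by -1.24 ± 0.12 log2 units and Ccnd1 by -0.80 ± 0.10. Of the 6 tested WNT target genes, 0 were higher, 4 were lower and 2 were not called, with 0 higher and 5 lower when adjusted over the list alone. The list of WNT target genes had a camera adjusted p = 0.000384, and adjusted p = 0.193 with an estimated correlation. In the trophoblast and keratin list, Gata2, also a BMP target above, Krt8 (-1.24 ± 0.11) and Tfap2a (-0.93 ± 0.12) were lower. Of the 5 tested trophoblast and keratin genes, 0 were higher, 4 were lower and 1 was not called, with 0 higher and 4 lower when adjusted over the list alone. The list of trophoblast and keratin genes had a camera adjusted p = 0.00279, and adjusted p = 0.193 with an estimated correlation. Among imprinted genes, Phlda2 changed by -2.13 ± 0.10, Peg3 by -0.98 ± 0.09 and the cell cycle inhibitor gene Cdkn1c by -0.85 ± 0.10, while Mest was higher by 0.79 ± 0.11. Of the 10 tested imprinted genes, 1 was higher, 7 were lower and 2 were not called, with 2 higher and 8 lower when adjusted over the list alone. With any 1 PGCLC array left out, 4 imprinted genes were lower. The list of imprinted genes had a camera adjusted p = 0.00494, and adjusted p = 0.193 with an estimated correlation. Of the primitive streak and mesoderm genes, Cdx2 was at least 3.00-fold lower, Evx1 changed by -1.82 ± 0.09, and Wnt3a was at least 2.10-fold higher, and the list had 1 higher, 3 lower and 3 not called (1 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.082).

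Some primed epiblast genes, DNA methylation genes and genes of glycolysis and hypoxia were higher in Nanog PGCLCs than in cytokine PGCLCs. Lefty1 was higher 4.56-fold (log2 fold change 2.19 ± 0.09), Cldn6 3.57-fold (log2 fold change 1.84 ± 0.17), Dnmt3b 1.58-fold (log2 fold change 0.66 ± 0.10) and Otx2, an epiblast transcription factor, 1.51-fold (log2 fold change 0.59 ± 0.10) (limma adjusted p from 6.27e-06 to 0.00463). Of the 9 tested primed epiblast genes, 5 were higher, 0 were lower and 4 were not called, with 6 higher and 2 lower when adjusted over the list alone. The list of primed epiblast genes had a camera adjusted p = 0.00505, and adjusted p = 0.193 with an estimated correlation. Fgf5 was at least 1.21-fold higher, a call lost without cytokine PGCLC replicate 1 (log2 fold change 0.44) or 2 (0.47) and without Nanog PGCLC replicate 1 (0.52) or 2 (0.39). It was also lost without background correction (0.17) and with the brighter arrays as a block (0.36). In the DNA methylation and oxidation list, Dnmt3l was higher by 0.39 ± 0.09 and Tet1, an enzyme that oxidizes methylcytosine, by 0.35 ± 0.10, and both calls were lost when any PGCLC array was left out. Without cytokine PGCLC replicates 1 and 2 and Nanog PGCLC replicates 1 and 2, in that order, Dnmt3l was at 0.435, 0.344, 0.38 and 0.398 and Tet1 at 0.351, 0.352, 0.354 and 0.349. Of the 7 tested DNA methylation and oxidation genes, 4 were higher, 0 were lower and 3 were not called, with 5 higher and 0 lower when adjusted over the list alone. The count higher was 1, 1, 2 and 1 without cytokine PGCLC replicate 1, cytokine PGCLC replicate 2, Nanog PGCLC replicate 1 and Nanog PGCLC replicate 2. The list of DNA methylation and oxidation genes had a camera adjusted p = 0.0125, and adjusted p = 0.295 with an estimated correlation, and it was not called without cytokine PGCLC replicate 2 (adjusted p = 0.0518, the highest of a range from 0.0038 over its 15 alternatives with the preset correlation). Pdk1 was higher by 0.94 ± 0.10, the muscle-type phosphofructokinase gene Pfkm by 0.54 ± 0.09 and the angiogenic factor gene Vegfa by 0.94 ± 0.15, the last not called without cytokine PGCLC replicate 2 (0.86). Of the 15 tested glycolysis and hypoxia genes, 6 were higher, 1 was lower and 8 were not called, with 6 higher and 1 lower when adjusted over the list alone. In the same order of arrays left out, the count higher was 4, 2, 3 and 4. The list of glycolysis and hypoxia genes had a camera adjusted p = 0.00681, and adjusted p = 0.193 with an estimated correlation.

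Early germ cell genes differed in both directions between the PGCLC groups. Dnd1 changed by -0.997 ± 0.09, Nanos3 by -0.83 ± 0.10 and Kit by -0.69 ± 0.10, while Rhox5 was higher in Nanog PGCLCs by 1.03 ± 0.11. Rhox6, named after its values were seen, was higher by 0.57 ± 0.11, a call lost without cytokine PGCLC replicate 1 (0.49) or Nanog PGCLC replicate 1 (0.49). Of the 15 tested early germ cell genes, 2 were higher, 7 were lower and 6 were not called, with 2 higher and 7 lower when adjusted over the list alone. The count lower was 4, 3, 4 and 5 without cytokine PGCLC replicate 1, cytokine PGCLC replicate 2, Nanog PGCLC replicate 1 and Nanog PGCLC replicate 2. The list of early germ cell genes had a camera adjusted p = 0.0879, and adjusted p = 0.295 with an estimated correlation. Tfap2c differed by -0.32 ± 0.09 (adjusted p = 0.039), a call lost with median scaling (-0.24) and with the brighter arrays as a block (-0.33). It was also lost without cytokine PGCLC replicate 1 (-0.36) or 2 (-0.28) and without Nanog PGCLC replicate 1 (-0.28) or 2 (-0.36), and the other Tfap2c probes gave 0.07 and -0.39. Dppa3 (0.18 ± 0.09) and Prdm14 (-0.16 ± 0.13) were not called, nor were Pou5f1 (-0.29 ± 0.10), Sox2 (0.30 ± 0.10), Esrrb (0.17 ± 0.09) and Zfp42 (0.17 ± 0.13), or Klf4, which was not detected in Nanog PGCLCs. Without background correction, with the authors' value table and with a variance trend, Pou5f1 (-0.29 to -0.27) and Sox2 (0.22 to 0.30) were called, as was Sox2 with an offset of 50 (0.28). The used Nanog probe differed by -0.38 ± 0.10 (adjusted p = 0.034), a call lost with median scaling (-0.30), with cyclic loess (-0.35) and without cytokine PGCLC replicate 1 (-0.38), cytokine PGCLC replicate 2 (-0.38) or Nanog PGCLC replicate 1 (-0.28). The core pluripotency list had 1 higher, 3 lower and 9 not called (3 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.849) and the naive list 4 higher, 2 lower and 9 not called (4 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.722), with Gbx2 higher by 1.396 ± 0.13. In the same order of arrays left out, 1, 1, 2 and 2 core genes were lower and 2, 2, 2 and 3 naive genes higher. LIF and STAT3 targets had 3 higher, 0 lower and 8 not called (3 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.0669). Of the PGCLC groups, LIF is listed for the cytokine PGCLCs only. The cholesterol synthesis list had 0 higher, 0 lower and 12 not called (0 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.519).

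Of the largest differences, Khdc3 was higher in Nanog PGCLCs 7.57-fold (log2 fold change 2.92 ± 0.14), the fatty acid carrier gene Fabp3 3.97-fold (log2 fold change 1.99 ± 0.10) and the transcription repressor gene Bhlhe40 at least 3.12-fold. Zscan4c, a cleavage-stage embryo gene, was at least 3.24-fold lower, the cyclin gene Ccnd2 at least 4.82-fold lower and Cxcl12 at least 4.07-fold lower. In all, 779 genes were higher and 760 lower (22.6%), and 82 were higher and 82 lower at least 2-fold by the fitted values, 64 of which were not detected on either array of the lower group. The counts depended on each PGCLC array, being 346 higher and 288 lower without cytokine PGCLC replicate 1, 361 and 315 without replicate 2, 422 and 446 without Nanog PGCLC replicate 1, and 444 and 397 without replicate 2. With median scaling 820 were higher and 477 lower (63.2% higher, against 50.6%), and without background correction 12 and 21 genes differed at least 2-fold.

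The changes of the PGCLC groups against mESCs were then set side by side. Across the 6823 genes, the log2 fold changes correlated at Pearson r = 0.821 and Spearman rho = 0.823. Both comparisons used the same 2 mESC arrays, and simulated unchanged groups against those arrays gave r = 0.497 on average and at most 0.567 in 100 draws. The covariance was 0.340 against 0.00723 in the simulation. Both groups had 1505 genes called higher, where independent lists would share 576, and 1238 called lower, where they would share 439. The shared mESC arrays push calls in both comparisons the same way, so the counts for independent lists, here and below, are no chance values. Of the 2743 genes called in the same direction, 605 also differed between the PGCLC groups, 57 of them at least 2-fold. Another 66 genes were called in opposite directions, where independent lists would give 1007, and this count fell to 36 and 38 without mESC replicate 1 or 2 and to 39 without either cytokine PGCLC array. In 17 of these 66 genes, 1 of the opposed directions lay between groups that were both below detection. With 1 mESC array for each PGCLC group, a split chosen after the data were seen, r was 0.755 and 0.773 in its 2 assignments, with covariances of 0.325 and 0.329. The split then gave 2088 and 2104 genes called in the same direction and 61 and 64 in opposite directions, each group resting on a lone mESC array assumed to vary like the PGCLC arrays.

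**Figure D3:**
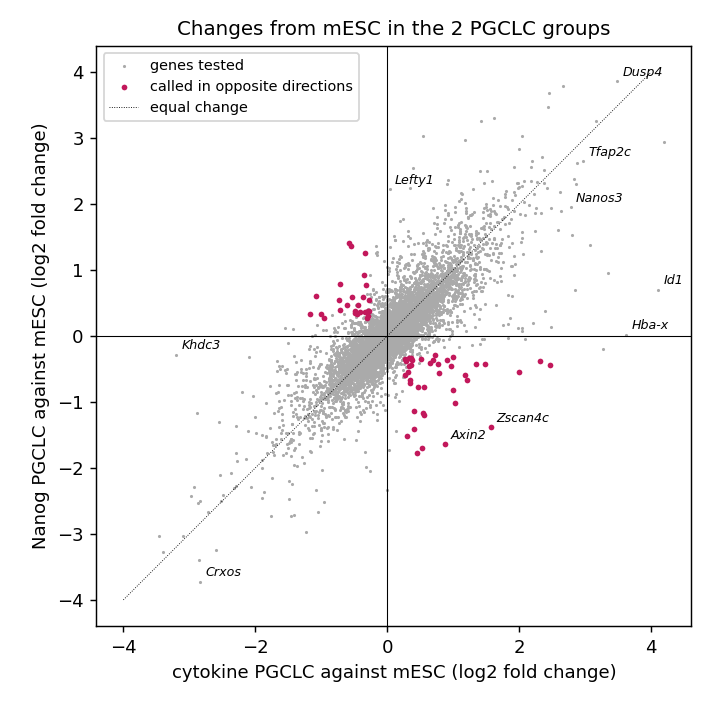
Log2 fold change against mESCs in Nanog PGCLCs (y axis) and in cytokine PGCLCs (x axis) for each of the 6823 genes, with a dotted line where both are equal and the 66 genes called in opposite directions in pink. The points spread along a rising band (r = 0.821), and Id1 and Hba-x lie far to the right of the dotted line, where their x values are fitted folds against an undetected level.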

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

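The tests of the Nanog probes and of the share of germ cells were chosen after the results were seen, and the test of blood genes was written after the globins but before the values it tests were seen.

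The second Nanog probe, which the gene's reported value does not use, was higher in Nanog PGCLCs than in mESCs by 1.14 ± 0.10 and than in cytokine PGCLCs by 1.80 ± 0.10 log2 units, while the used probe was at -0.26 and -0.38. The gap between the probes moved by 2.18 ± 0.16 between the PGCLC groups, and 0.05% of 1905 genes with several probes (1 gene, Nanog itself) had a gap as wide, which argues against ordinary spread between probes. Against mESCs the gap in Nanog PGCLCs was 1.399 ± 0.16, and 47 genes (2.47%) had one as wide, so spread between probes is not argued against there, and a transgene transcript read by only 1 probe may account for this part but stays open, since where the probes lie is not known here. The rest of the gap between the PGCLC groups is the -0.779 ± 0.16 between cytokine PGCLCs and mESCs, neither of which is labelled as given doxycycline. A transgene transcript does not account for this rest if the transgene is silent without doxycycline, which was not tested. There 10.2% of genes had a gap as wide. A change of the cells' own Nanog transcript between groups is a biological alternative that was not tested.

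The embryonic globin genes were detected in cytokine PGCLCs only, with raw intensities of 659 and 686 for Hba-x against 158 and 193 in mESCs and 161 and 197 in Nanog PGCLCs, while Hbb-bh1 read 867 and 879 in cytokine PGCLCs against 207 and 323 in Nanog PGCLCs, and Hbb-y 709 and 671 against 233 and 309. Hba-a1 read 659 and 695 against 266 and 378, but 2752 on mESC replicate 1. Blood cells or their RNA in the cytokine PGCLC arrays may be a source, but only 4 of 36 further red cell genes written down for the test were measured, and their median lay at percentile 78.6 of 10000 random lists. As Nanog minus cytokine, Alad (-0.49 ± 0.10) and Blvrb (0.35 ± 0.09) were called, calls lost without cytokine PGCLC replicate 1 (-0.52 and 0.373), cytokine PGCLC replicate 2 (-0.467 and 0.333) or Nanog PGCLC replicate 1 (-0.472 and 0.351) and for Blvrb without Nanog PGCLC replicate 2 (0.355), Urod (-0.33 ± 0.12) and Tfrc (0.09 ± 0.10) were not, though Urod was called without background correction (-0.306), with the authors' table (-0.308) and with a variance trend (-0.333), and all 4 were detected on both mESC arrays, so the test decides nothing. Sptb, of the red cell skeleton (-1.26 ± 0.14), and the iron exporter gene Slc40a1 (-0.56 ± 0.10) were also lower in Nanog than in cytokine PGCLCs. Both were left out of the test because they had been seen, as were 3 further genes, Pecam1, Kdr and Lyl1. Of the 5 tested members of the endothelial and blood list, Hba-x, Hbb-bh1 and Hba-a1 are globins. None of the few other members was called between the PGCLC groups. Genes already seen thus do not decide on blood cells, for or against. A response to the BMP proteins, given to the cytokine PGCLCs alone, was not tested. Nor was a response to SCF, EGF or LIF, which the Nanog PGCLCs are not listed as given.

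Of the 15 tested early germ cell genes, 2 were higher and 7 lower in Nanog than in cytokine PGCLCs, with 4, 3, 4 and 5 lower without cytokine PGCLC replicate 1, cytokine PGCLC replicate 2, Nanog PGCLC replicate 1 and Nanog PGCLC replicate 2, and the list was not called (camera adjusted p = 0.0879, and adjusted p = 0.295 with an estimated correlation). A smaller share of germ cell-like cells in the Nanog PGCLC arrays may lower such genes, so the 7 members whose mean over both PGCLC groups was at least 2-fold above mESCs were taken, and their common shift was -0.327 ± 0.207, within 2 standard errors of 0. That error was widened for the spread between members, which went far beyond their own errors (heterogeneity Q = 184.5). The members thus did not move by a common amount, which the test asked of a smaller share. Their shifts ran from -0.997 for Dnd1 to 0.57 for Rhox6, whose call was lost without cytokine PGCLC replicate 1 (0.486) or Nanog PGCLC replicate 1 (0.494). Single genes decide nothing here, because the level of each gene in the other cells was not measured, so a smaller share stays open. A difference between Nanog and cytokine induction also stays open and was not tested apart from it.

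Against mESCs, 66 genes were called in opposite directions in the PGCLC groups and also differed between those groups, 26 of them higher in Nanog PGCLCs and 40 higher in cytokine PGCLCs, and the count was 36 and 38 without mESC replicate 1 or 2 and 39 without either cytokine PGCLC array. Probes without a gene name, which the comparisons of the report leave out, included 344 called higher and 292 called lower in Nanog PGCLCs than in mESCs, of 1359 tested. In cytokine PGCLCs 363 such probes were called higher and 319 lower than in mESCs.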

How the results depend on the processing

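The block for the 2 brighter arrays, and all alternatives to the 2-fold counts, to the overlap counts, to each list and its members and to genes named after their values were seen, were chosen after the data were seen. Over the 349 gene results and their alternatives, 5668 values kept their direction and side of the threshold, 230 fell short of it, 25 passed it newly and 10 reversed, and for the 17 called lists 253 kept it, 19 fell short and 0 reversed. No gene called in the reported fit was called in the opposite direction under any setting that was run for single genes (0 in each). The cause of the changes below was not tested unless stated.

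At an adjusted p below 0.01, fewer genes were called by construction, with 1166 lower in Nanog PGCLCs and 1088 lower in cytokine PGCLCs than in mESCs, and 349 higher and 317 lower between the PGCLC groups. Every probe by itself gave 2685 and 2666 lower than in mESCs and 718 higher and 382 lower at least 2-fold in Nanog and 724 and 405 in cytokine PGCLCs, since more features were tested. Without background correction, the counts at least 2-fold higher and lower were 101 and 55, 82 and 68, and 12 and 21 in the order of the report, and with the authors' values they were 105 and 68, 92 and 83, and 12 and 28. An offset of 50 gave 53 genes at least 2-fold higher between the PGCLC groups. Median scaling moved the median of all genes by 0.21, 0.152 and 0.06 log2 units, from -0.004, 0.011 and -0.02, and it called fewer genes lower (854, 973 and 477), and it gave 721 higher and 144 lower at least 2-fold in Nanog PGCLCs against mESCs. For cytokine PGCLCs against mESCs, 7 lists were called without background correction, with median scaling, with the authors' table and with a variance trend, and 5 with cyclic loess. With an estimated correlation 0, 0 and 0 lists were called. The correlation of the profiles was 0.813 with cyclic loess and 0.813 with the authors' table.

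All values that reversed were of genes not called in the reported fit, except Sox7. Zfp42 in Nanog PGCLCs against mESCs was at -0.063 with cyclic loess, and Fgf5 in cytokine PGCLCs against mESCs, undetected in both, at 0.084 with median scaling and 0.074 with the brighter arrays as a block. Sox7, called lower in Nanog PGCLCs than in mESCs at -0.262, was at 0.019 with median scaling. Its call was also lost without background correction (-0.105), with an offset of 50 (-0.213), cyclic loess (-0.158) and the authors' table (-0.117), and at an unchanged value with both other filters, a variance trend and only the groups compared. It was lost too without mESC replicate 1 (-0.228) or 2 (-0.296), either cytokine PGCLC array (-0.262) or Nanog PGCLC replicate 2 (-0.186). When 1 array was left out, Klf4 ran from -0.256 to 0.062 between the PGCLC groups and Zfp42 from -0.023 to 0.373, and in cytokine PGCLCs against mESCs Zfp42 ran from -0.324 to 0.072, reversed without cytokine PGCLC replicate 2. Fgf5 there ran from -0.151 to 0.106, reversed without mESC replicate 2. In Nanog PGCLCs against mESCs, Esrrb ran from -0.002 to 0.116 and Pou5f1 from -0.069 to 0.002, reversed without Nanog PGCLC replicate 1.

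Leaving out 1 array at a time left a lone array that is assumed to vary like the other groups. Between the PGCLC groups 346 to 806 genes were then higher and 288 to 784 lower, the fewest without cytokine PGCLC replicate 1. The genes higher and lower were 1633 to 1819 and 1370 to 1626 in Nanog PGCLCs and 1584 to 2011 and 1216 to 1673 in cytokine PGCLCs against mESCs. Lists called in cytokine PGCLCs against mESCs numbered 3 to 5, and the profile correlation was 0.811 to 0.827. Genes called in opposite directions numbered 36 to 55. The replicate numbers did not pair the arrays (correlations of deviations 0.036, 0.079 and -0.004), and with the replicate block 1931 and 1768, 2038 and 1693, and 772 and 745 genes were higher and lower. With the brighter arrays as a block 1961 and 1820, 1923 and 1553, and 617 and 572 were higher and lower. Signal over background limits the folds of genes near detection, which is why bounds are given for them.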

Other observations

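The oxidative stress and actin hypotheses were prompted by genes already seen to be lower than in mESCs, which were left out, and their tests were written before the values of the remaining genes were seen.

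Of the 8 tested FGF and ERK target genes, 5 were higher and 1 lower in Nanog PGCLCs than in mESCs, 4 and 0 in cytokine PGCLCs than in mESCs, and 0 and 3 in Nanog than in cytokine PGCLCs, or 5 and 2, 4 and 0, and 2 and 3 adjusted over the list alone (camera adjusted p = 0.0997, 0.0757 and 0.722). The count lower between the PGCLC groups was 2, 1, 1 and 1 without cytokine PGCLC replicate 1, cytokine PGCLC replicate 2, Nanog PGCLC replicate 1 and Nanog PGCLC replicate 2. Egr1, an early response gene of ERK signalling, was at least 1.75-fold higher in Nanog PGCLCs and at least 2.41-fold higher in cytokine PGCLCs than in mESCs, and Dusp6, a phosphatase that acts on ERK, was higher by 1.13 ± 0.09 and 1.69 ± 0.09 log2 units. The MEK inhibitor PD0325901 is listed for the mESCs only, so these differences from mESCs cannot be told apart from the change of medium. Between the PGCLC groups, BMP4, BMP8A, SCF, EGF, LIF and doxycycline differ, so the difference there cannot be assigned to any of them alone. Of the 7 tested cell adhesion and EMT genes, 3 were higher and 2 lower in Nanog PGCLCs than in mESCs, 3 and 3 in cytokine PGCLCs than in mESCs, and 3 and 2 in Nanog than in cytokine PGCLCs, or 3 and 2, 3 and 3, and 3 and 2 adjusted over the list alone (camera adjusted p = 0.504, 0.938 and 0.329), with a median of -0.16 but a mean of 0.12 in the second of these. The epithelial splicing factor gene Esrp1 was higher 5.72-fold and 5.21-fold against mESCs, and the tight junction genes Cldn4 and Cldn3 were higher in Nanog than in cytokine PGCLCs by 1.43 ± 0.10 and 0.69 ± 0.12. Of the 14 tested histone methylation genes, 4 were higher and 7 lower in Nanog PGCLCs than in mESCs, 3 and 3 in cytokine PGCLCs than in mESCs, and 0 and 4 in Nanog than in cytokine PGCLCs, or 4 and 7, 3 and 3, and 0 and 5 adjusted over the list alone (camera adjusted p = 0.504, 0.938 and 0.199). Without Nanog PGCLC replicate 1, 4 were lower than in mESCs in Nanog PGCLCs, and with any 1 PGCLC array left out 1 was lower between the PGCLC groups. The demethylase gene Kdm2b changed by -0.57 ± 0.09 against mESCs in Nanog PGCLCs (not called with median scaling, -0.249), while Suz12, a subunit of the Polycomb complex that methylates histone H3, was higher by 0.51 ± 0.09 there and by 0.48 ± 0.09 in cytokine PGCLCs. Of the 6 tested late germ cell and meiosis genes, 1 was higher and 2 lower in Nanog PGCLCs than in mESCs, 1 and 3 in cytokine PGCLCs than in mESCs, and 1 and 1 in Nanog than in cytokine PGCLCs, or 1 and 2, 1 and 3, and 1 and 1 adjusted over the list alone (camera adjusted p = 0.504, 0.465 and 0.745). Tex19.1, which restrains transposons in germ cells, changed by -1.78 ± 0.10 and -1.53 ± 0.10 against mESCs. Ddx4, called lower in Nanog PGCLCs than in mESCs, was not called with median scaling (-0.017), cyclic loess (-0.217) or no background correction (-0.151). Its call was also lost without mESC replicate 1 (-0.344), mESC replicate 2 (-0.336) or Nanog PGCLC replicate 1 (-0.243). Tuba3a was called higher in Nanog than in cytokine PGCLCs. Its call was lost without cytokine PGCLC replicate 2 (0.356), Nanog PGCLC replicate 1 (0.527) or Nanog PGCLC replicate 2 (0.499).

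Of the 11 tested p53 target and apoptosis genes, 3 were higher and 4 lower in Nanog PGCLCs than in mESCs, 3 and 3 in cytokine PGCLCs than in mESCs, and 2 and 1 in Nanog than in cytokine PGCLCs, or 3 and 4, 3 and 4, and 3 and 5 adjusted over the list alone (camera adjusted p = 0.557, 0.831 and 0.836). Their median was below 0 and their mean above it in both comparisons with mESCs (-0.20 and 0.04, and -0.16 and 0.07). Bcl2l11, which promotes cell death, was higher in Nanog PGCLCs at least 3.81-fold and in cytokine PGCLCs at least 2.24-fold, and the cell cycle inhibitor gene Cdkn1a changed by -0.86 ± 0.10 in Nanog PGCLCs. Gadd45a was called higher in Nanog than in cytokine PGCLCs, but not with both other filters, the replicate block and only the groups compared (0.303 in each). The call was also lost when any PGCLC array was left out, with differences from 0.267 to 0.339. Of the 11 tested stress and immediate early genes, 2 were higher and 4 lower in Nanog PGCLCs than in mESCs, 2 and 2 in cytokine PGCLCs than in mESCs, and 2 and 3 in Nanog than in cytokine PGCLCs, or 2 and 4, 2 and 2, and 2 and 4 adjusted over the list alone (camera adjusted p = 0.504, 0.728 and 0.437), and in the second the median was -0.12 but the mean 0.04. Without mESC replicate 1 or Nanog PGCLC replicate 1, 2 were lower in Nanog PGCLCs than in mESCs, and between the PGCLC groups 1 was lower without cytokine PGCLC replicate 2 or Nanog PGCLC replicate 1. The heat shock gene Hspb1 changed by -0.56 ± 0.12 and -1.23 ± 0.12 against mESCs. Of the 17 tested cell cycle genes, 2 were higher and 4 lower in Nanog PGCLCs than in mESCs, 3 and 5 in cytokine PGCLCs than in mESCs, and 1 and 1 in Nanog than in cytokine PGCLCs, or 2 and 4, 3 and 5, and 1 and 1 adjusted over the list alone (camera adjusted p = 0.504, 0.724 and 0.519), with Top2a, which untangles replicated DNA, higher by 0.74 ± 0.09 and 1.12 ± 0.09 against mESCs. In the cell cycle list, 2 were lower in Nanog PGCLCs than in mESCs without mESC replicate 1, mESC replicate 2 or Nanog PGCLC replicate 2, and 3, 2 and 1 in cytokine PGCLCs without mESC replicate 1, mESC replicate 2 or cytokine PGCLC replicate 1. Of the 19 tested oxidative phosphorylation genes, 4 were higher and 1 lower in Nanog PGCLCs than in mESCs, 3 and 1 in cytokine PGCLCs than in mESCs, and 3 and 0 in Nanog than in cytokine PGCLCs, or 2 and 1, 3 and 1, and 0 and 0 adjusted over the list alone (camera adjusted p = 0.504, 0.938 and 0.519), with Uqcrq, a subunit of respiratory complex III, at -0.71 ± 0.11 and -0.67 ± 0.11 against mESCs. The 4 higher in Nanog PGCLCs than in mESCs became 1, 2 and 2 without mESC replicate 2, Nanog PGCLC replicate 1 or Nanog PGCLC replicate 2, and the 3 higher between the PGCLC groups became 0, 1, 0 and 1 without cytokine PGCLC replicate 1, cytokine PGCLC replicate 2, Nanog PGCLC replicate 1 and Nanog PGCLC replicate 2.

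The remaining lists had too few measured members for a test. Of the 4 tested endoderm genes, 1 was higher and 2 lower in Nanog PGCLCs than in mESCs, 2 and 1 in cytokine PGCLCs than in mESCs, and 1 and 2 in Nanog than in cytokine PGCLCs, or 1 and 2, 2 and 1, and 1 and 3 adjusted over the list alone. These calls were fragile, Sox7 as given above. In cytokine PGCLCs against mESCs, Dab2 was not called with the authors' table (0.146). Without cytokine PGCLC replicate 2, the calls of Apoe (0.51) and Dab2 (0.339) were lost. That of Apoe was also lost without cytokine PGCLC replicate 1 (0.564) or mESC replicate 1 (0.303). Between the PGCLC groups, the call of Apoe was lost when any PGCLC array was left out (0.601 to 0.738). Of the 4 tested neural and surface ectoderm genes, 0 were higher and 2 lower in Nanog PGCLCs than in mESCs, 0 and 1 in cytokine PGCLCs than in mESCs, and 0 and 1 in Nanog than in cytokine PGCLCs, or 0 and 2, 0 and 1, and 0 and 1 adjusted over the list alone. Of the 4 tested fibroblast and matrix genes, 0 were higher and 2 lower in Nanog PGCLCs than in mESCs, 1 and 2 in cytokine PGCLCs than in mESCs, and 0 and 3 in Nanog than in cytokine PGCLCs, or 0 and 2, 2 and 2, and 0 and 3 adjusted over the list alone, with Acta2 at -1.86 ± 0.17 against mESCs in Nanog PGCLCs. Between the PGCLC groups 1 of these was lower without cytokine PGCLC replicate 1. Of the 3 tested Hox genes, 0 were higher and 1 lower in Nanog PGCLCs than in mESCs, 0 and 0 in cytokine PGCLCs than in mESCs, and 0 and 1 in Nanog than in cytokine PGCLCs, or 0 and 1, 0 and 0, and 0 and 2 adjusted over the list alone. Of the 3 tested cleavage stage genes, 0 were higher and 3 lower in Nanog PGCLCs than in mESCs, 2 and 1 in cytokine PGCLCs than in mESCs, and 0 and 2 in Nanog than in cytokine PGCLCs, or 0 and 3, 2 and 1, and 0 and 2 adjusted over the list alone, with Zscan4c at least 2.79-fold higher in cytokine PGCLCs than in mESCs.

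Of the 66 genes called in opposite directions against mESCs, those in this paragraph were chosen after their values were seen. The receptor gene Fzd10 was at -0.81 in Nanog PGCLCs and 1.00 in cytokine PGCLCs (SE 0.10, log2 fold change against mESCs), and the secreted inhibitor gene Sfrp1 at 0.34 and -1.17 (SE 0.09), the first not called without mESC replicate 2 (0.289). Mycl, a relative of Myc, was at -1.01 and 1.03 (SE 0.09).

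One hypothesis was that oxidative stress response genes were lower in both PGCLC groups than in mESCs, prompted by Gpx2, Gsto1, Gss and Cbr3. Of 27 genes written down, 18 were measured, and in Nanog PGCLCs 4 were higher and 4 lower, with a median of 0.093 (0.019 with the undetected gene at its bound, bootstrap SE 0.14), within its spread of 0. In cytokine PGCLCs 3 were higher and 10 lower, with a median of -0.39 (camera adjusted p = 0.0488 over 6 tests, and adjusted p = 0.189 with an estimated correlation). The rule written beforehand counts a median at or above 0 in either group against the hypothesis, and the 0.093 in Nanog PGCLCs meets it. A lower level in both groups was thus not shown, although a median within its spread of 0 does not firmly exclude it. Between the PGCLC groups 8 were higher and 0 lower in Nanog PGCLCs, with a median of 0.30 (camera adjusted p = 0.000209, and adjusted p = 0.161 with an estimated correlation). Among them the thioredoxin gene Txn1 was higher by 1.16 ± 0.14 and the ferritin gene Ftl1 by 0.69 ± 0.10, both named after their values were seen.

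A second hypothesis was that actin cytoskeleton and YAP target genes were lower in both PGCLC groups, prompted by Acta2, Myl9, Vim, Emp1 and Ccn2, and 13 of 31 genes written down were measured. In Nanog PGCLCs 2 were higher and 7 lower, with a median of -0.492 (bootstrap SE 0.36, camera adjusted p = 0.163, and adjusted p = 0.256 with an estimated correlation). In cytokine PGCLCs 2 were higher and 8 lower, with a median of -0.76 (camera adjusted p = 0.043, and adjusted p = 0.186 with an estimated correlation). The hypothesis stays open, since the list was not called in Nanog PGCLCs. Between the PGCLC groups 4 were higher and 1 lower in Nanog PGCLCs, with a median of 0.19 (camera adjusted p = 0.043, and adjusted p = 0.186 with an estimated correlation). Apart from the correlation, preset or estimated, no other setting was tried for these hypotheses.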
